A study of Mus musculus with 2 samples.

How the data were processed

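H3K4me2 ChIP-seq peak lists from embryonic day 12.5 mouse liver were analysed: 2 biological replicates of 1 group, from pools of 120 and 88 embryos of both sexes, with library sizes of 300 to 500 bp per the labels. Per the deposited text that describes the files, the authors called peaks on each replicate alone and on both together, from alignments to mm10 and control alignments, and made a list of replicated peaks from these. The peak caller, its version and threshold and the rule for replicated peaks were not given in the sources used here. Every replicated peak was found to be an interval of the pooled list. In each deposited list the authors gave a fold enrichment over control (a ratio), a −log10 p-value and a −log10 q-value per peak. These are the authors' values and were used to describe, rank or filter peaks. The smallest −log10 p in the lists was 2.01. No read counts were used, so sequencing depth is unknown and no interval for counting error is given.

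Peaks on the 21 assembled chromosomes were used, and 11 (replicate 1), 15 (replicate 2), 12 (pooled) and 11 (replicated) peaks on other scaffolds were left out of the comparisons. No peak extended past a chromosome end of the reference, the primary assembly of GRCm38, which has the mm10 coordinates, with GENCODE M21 gene models. The TSS of a gene's transcript with the longest coding sequence was used for breadth and distal counts, and all annotated TSSs for promoter peaks. A promoter was 1 kb to each side of a TSS. Breadth was the number of peak bases within 5 kb to each side. Distal peaks had no base within 2.5 kb of any TSS and were counted within 50 kb. Domains were replicated peaks merged over gaps of up to 1 kb. Promoter CpG content was the ratio of observed to expected CpG within 500 bp of the TSS. Peaks shared between replicates overlapped by at least 1 bp, and expected values came from 100 circular shifts within chromosomes.

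The 18 gene lists, 17 consensus sites, tests and alternatives were fixed before the data were examined, except for those given here as chosen or set after the data or values were seen and for the promoter share, where more random lists were drawn than planned. Lists were compared with other coding genes by a two-sided Fisher's exact test, and by two-sided permutation tests against 100000 random lists with the same number of genes per CpG decile. A call is an adjusted p under 0.05, or for sites a 95% interval that excludes 1. The p-values were adjusted by the Benjamini-Hochberg method over the 18 lists of each measure. The smallest p these permutations can give is 2e-05 before adjustment. Genes are not replicates, and neighbours in a list can share peaks, which makes p too small. These tests describe the present libraries. Hoxa9 was the only gene in 2 lists. Sites were counted on both strands in distal peaks and in windows of the same width 3 kb to each side without a pooled peak, with 95% intervals from 1000 bootstraps over peaks. A ratio was given where flanks held at least 10 matches, a minimum set after the values were seen.

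Genes were named by rule: in each list but the Hox and receptor lists the 2 with the most covered bases and the first 2 in alphabetical order without a promoter peak in either replicate. Added to these were the 10 genes under the broadest promoter domains, the genes nearest to the 5 highest peaks, the 5 listed genes with the highest fold enrichment among those marked in 1 replicate, and a fixed set of globin, other blood and liver genes. Alternatives included other windows, −log10 q of at least 5, other overlaps, no CpG matching, and each replicate's list alone. Alternatives chosen after the data were seen left receptor genes out of the background, left globin genes out, or kept only genes with no other coding TSS within 5 kb.

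The list test was tested on simulated data for promoter breadth of 21938 genes. Of 200 unchanged lists of 20 genes, 4.5% had an unadjusted p under 0.05. The share was 75.5% for lists raised 2 times and 99.5% for lists raised 4 times. The simulated values were independent between genes, without an upper limit or the many zeros of the data. These shares therefore do not show how the test performs for genes that share peaks or after adjustment of p. A site planted in simulated peaks at 3 times its flank density was measured at 2.93 times (95% interval 2.90 to 2.95, which lies below 3), and a site that was not planted at 1.38 times (0.981 to 1.89) in the same 400 peaks. The 896 overlapping pairs in simulated intervals were those that bedtools gave. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and, for that check of overlaps, bedtools 2.31.1.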

Results

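Chromatin from the livers of mouse embryos at embryonic day 12.5 (strain B6NCrl) was immunoprecipitated for H3K4me2, the dimethylated form of histone H3 lysine 4, which is found at promoters and enhancers. The embryonic liver at this stage is a site of blood formation and holds erythroid and other blood cells beside hepatoblasts. There was 1 group with 2 biological replicates, made from 120 and 88 pooled embryos of both sexes, so the data hold no contrast between groups. The comparisons are between the replicates, between gene lists and between regions of the genome. Peak positions and heights were those deposited by the authors, on mm10. Numbers of reads were not given in the sources used here, so the depth behind each peak is unknown. The files list called peaks, so a gene without a peak had none called, which does not show that the mark was absent. Values given as mean ± SD are those of the 2 replicates' own lists, and other values, unless stated, come from the authors' list of replicated peaks, made by a rule not given in the sources used here.

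H3K4me2 peaks lay at the promoters of most genes, and the broadest domains included several over erythroid genes. The broadest domain at a promoter covered 51313 bp at Zfpm1, which encodes a partner of the erythroid factor GATA1 (chromosome 8, 122280042 to 122331354). The next ran for 36158 bp inside Ank1, which encodes erythrocyte ankyrin (chromosome 8, 23026850 to 23063007). It was followed by 25808 bp at Ranbp10 and Tsnaxip1, 25108 bp at Slc30a10, 25033 bp at Stradb and Trak2, and 24467 bp over the alpha-globin genes Hba-x, Hba-a1 and Hba-a2 (chromosome 11, 32277635 to 32302101). The highest peaks by the authors' fold enrichment over control were at Cnnm2 (77.3), the apoptosis gene Bbc3 (74.4), the blood stem cell regulator Runx1 (73.9), Iqsec1 (73.5) and Sgpl1 (71.4), each overlapping an annotated transcription start site (TSS). Replicate 1 had 55879 peaks and replicate 2 had 52727 on the assembled chromosomes, covering 62.8 Mb and 61.4 Mb. The list called on both replicates together had 58562 peaks and the replicated list 42960, covering 70.5 Mb and 66.5 Mb.

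The replicates marked largely the same regions. Of the replicate 1 peaks, 44975 (80.5%) overlapped a replicate 2 peak, and 44617 (84.6%) of the replicate 2 peaks overlapped a replicate 1 peak. Shifting the lists along the chromosomes gave 4.34 ± 0.249% and 4.52 ± 0.219% (SD over 100 shifts). Shared bases made up 79.7% of the bases covered by either replicate, against 1.31% after shifting. Peaks without a partner were weaker and narrower: in replicate 1 their median fold enrichment was 2.82 and their median width 233 bp, against 6.94 and 894 bp for shared peaks, and in replicate 2 the values were 3.08 and 228 bp against 7.71 and 879 bp. In the decile with the lowest −log10 q, 38.3% of replicate 1 and 46.0% of replicate 2 peaks were shared, and in the 4 highest deciles 100% were. Fold enrichment in the replicates was correlated across 39824 replicated peaks with a Spearman coefficient of 0.927 and a Pearson coefficient of 0.945 on the log2 scale. These are correlations across peaks, which are not independent replicates. Fold enrichment was higher in replicate 2 by a median of 0.21 on the log2 scale, with an SD of 0.46 across peaks. Of 332 listed genes, without the Hox and receptor lists, 22 had a promoter peak in 1 replicate only. The 5 with the highest fold enrichment there, at 3.22 to 4.22, were the heart actin gene Actc1, the platelet receptor gene Clec1b, the matrix gene Lum, the leukocyte gene Ptprc and the neuronal gene Stmn2.

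**Figure D1:**
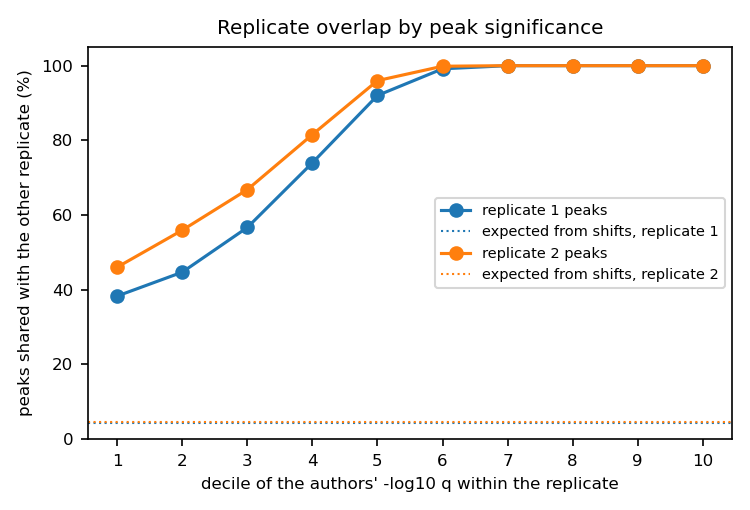
Percentage of each replicate's H3K4me2 peaks that overlap a peak of the other replicate (vertical axis) by decile of the authors' −log10 q within that replicate (horizontal axis); dotted lines are the means expected from circular shifts. The share rose from 38.3% and 46.0% in the lowest decile to 100% in the 4 highest.

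The replicated list kept the stronger, promoter-rich part of the pooled list. It held 42960 (73.4%) of the 58562 pooled peaks, each with an identical interval. Kept peaks had a median fold enrichment of 8.05 and a median width of 1063 bp, and 46.8% overlapped a promoter. The 15602 peaks left out had 2.5, 233 bp and 16.9%. Of the kept peaks, 39736 (92.5%) shared at least 50% of the shorter interval with a peak in both replicates, 3109 with a peak in 1 replicate only and 115 with neither. Of those left out 0 did so in both replicates and 9754 in 1. The share kept rose to 96.0% among pooled peaks with −log10 q of at least 5.

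Promoters, taken as 1 kb to each side of any annotated TSS, held 46.8% of replicated peaks, against 10.1% after shifting. Intergenic regions held 19.7% against 49.9%, introns 29.4% against 37.1% and exons 4.02% against 2.83%. In the replicates' own lists 41.7 ± 0.827% (SD, n = 2) of peaks were at promoters. Promoter peaks were broader and higher than distal ones, with a median width of 1980 bp against 729 bp and a median fold enrichment of 25.1 against 4.78. Distal peaks, with no base within 2.5 kb of a TSS, numbered 18775 (43.7%). A promoter peak was found at 15118 of 21938 protein-coding genes (68.9%), and at 69.2 ± 0.0161% (SD, n = 2) in the replicates. The share followed promoter CpG content, from 8.48% in the decile of genes with the lowest ratio of observed to expected CpG to 99.6% in decile 9. The share of peaks at promoters depended on the list and window used, from 38.8% in the pooled list to 56.3% with 2.5 kb to each side.

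Erythroid genes were marked almost without exception, while most genes of mature hepatocytes and of macrophages and granulocytes were not. Of 30 erythroid genes, 29 had a promoter peak (96.7% in each replicate too), including Gata1, Klf1, Tal1, Nfe2, all 3 listed alpha-like and all 4 listed beta-like globin genes, against 68.9% of other genes (two-sided Fisher's exact test, adjusted p = 0.000964). The promoter peaks of the embryonic globin genes Hba-x and Hbb-y were low, with fold enrichments of 2.48 and 2.44. With −log10 q of at least 5 the erythroid share was 90% (adjusted exact p = 0.015). Of 26 hepatoblast genes 23 were marked (88.5%, and 90.4 ± 2.72% in the replicates, SD, n = 2, adjusted exact p = 0.0456), among them Alb and Afp, which encode albumin and alpha-fetoprotein, and the liver factors Hnf4a, Prox1 and Foxa3. The promoter peaks of Alb and Afp were low, with fold enrichments of 4.06 and 3.07 against a median of 25.1 for promoter peaks. Only 6 of 23 genes of mature hepatocyte metabolism were marked (26.1%, and 28.3 ± 3.07% in the replicates, SD, n = 2, adjusted exact p = 0.000178). The ammonia-handling genes Glul and Ass1 were marked, and the bile salt exporter gene Abcb11 and the urea cycle gene Cps1 were not. Of 21 macrophage and granulocyte genes 3 were marked (14.3%, and 23.8 ± 6.73% in the replicates, SD, n = 2, adjusted exact p = 3.06e-06), and the complement genes C1qa and C1qb were not. Both calls ended against random lists matched on promoter CpG content, where the matched means were 34.2% for mature hepatocyte genes (adjusted permutation p = 0.74) and 24.3% for macrophage and granulocyte genes (0.656). The hepatoblast call was lost without replicate 2 (88.5%, adjusted exact p = 0.050002) and with receptor genes left out of the background, a setting chosen after the data were seen (adjusted exact p = 0.165).

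Of 20 haematopoietic stem and progenitor genes 18 were marked, including Lmo2, Meis1, Runx1 and Spi1 but not Slamf1, and the list did not pass the test (90.0%, adjusted exact p = 0.0653), although it did without replicate 1 (95%, adjusted exact p = 0.0176). Megakaryocyte genes numbered 13 of 17 (adjusted exact p = 0.611), with Itga2b and Tubb1 marked and Gp6 and Ppbp not. Lymphoid genes numbered 7 of 18 (adjusted exact p = 0.0153), with Bcl11b and Ebf1 marked and the B and T cell genes Cd19 and Cd3e not. Endothelial genes numbered 14 of 18 (adjusted exact p = 0.611), with Esam and Egfl7 marked and Lyve1 and Robo4 not. Mesenchymal and stellate genes numbered 17 of 19 (adjusted exact p = 0.0945, and 0.0396 with the TSS of the longest coding sequence only), with Reln and Gata4 marked and the collagen gene Col3a1 not. Cholangiocyte genes numbered 12 of 14 (adjusted exact p = 0.282), with Onecut2 and Cd24a marked and Spp1 not.

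Further lists of genes with CpG-rich promoters were also marked: 19 of 20 neural genes (adjusted exact p = 0.0193), 25 of 26 transcription factors of other lineages (adjusted exact p = 0.00224) and 36 of 39 Hox genes (adjusted exact p = 0.00201). Gfap and Nes were among the marked neural genes, and the neuronal gene Dcx and the homeobox gene Lhx5 were exceptions. All 23 housekeeping genes (adjusted exact p = 0.00107) and all 20 cell cycle genes (adjusted exact p = 0.00219) had a promoter peak. Muscle and heart genes had one at 5 of 19 (adjusted exact p = 0.000744), with Mylpf and Ryr1 marked and Acta1 and Casq1 unmarked. Mylpf has the TSSs of Sept1 and Tbc1d10b within 5 kb. Pluripotency and germline genes had one at 6 of 18 (adjusted exact p = 0.00582), with Sox2 and Esrrb marked and Dppa4 and Dmrtb1 not. In the replicates these shares were 31.6 ± 7.44% and 41.7 ± 11.8% (SD, n = 2). Of 1420 olfactory and vomeronasal receptor genes 6 had one. The neural call was lost with 500 bp windows, without replicate 1 and without receptor genes (adjusted exact p = 0.0611, 0.0656 and 0.0587), that of transcription factors of other lineages with the TSS of the longest coding sequence only (84.6%, 0.051), and the pluripotency call without replicate 2 (50%, 0.156).

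Against random lists matched on promoter CpG content, by permutation, 5 lists stood apart. The 3 above were erythroid, hepatoblast and megakaryocyte genes, with matched means of 45.1% for the erythroid (adjusted permutation p = 0.00012), 57.5% for the hepatoblast (0.00081) and 39.4% for the megakaryocyte list (0.00338). Below stood pluripotency and germline genes, with a matched mean of 84.3%, and receptor genes, with 18.1% (both adjusted permutation p = 0.00012, from the smallest p the random lists allow). The other 13 lists did not pass, with adjusted permutation p of at least 0.111 (mesenchymal and stellate). Among them were lists with a call by Fisher's exact test. Of these, the matched mean was 45.8% for lymphoid, 41.9% for muscle and heart, 86.4% for neural and 89.7% for Hox genes. It was 93.9% for transcription factors of other lineages, and 96.0% for both housekeeping and cell cycle genes. Receptor genes made up 20.6% of the genes in the 3 lowest CpG deciles, which lowers the matched means of lists with CpG-poor promoters. The matched comparison of promoter shares was not repeated without receptor genes.

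Erythroid genes had the highest mean H3K4me2 breadth of the 18 lists. Peaks covered 5950.4 ± 76.7 bp (SD, n = 2) within 5 kb to each side of their TSS, and in the replicated list 6211 bp, which was 4.61 times the mean of random lists matched on promoter CpG content (two-sided permutation test, adjusted p = 6e-05, from the smallest p that 100000 lists allow). Of the 30 genes, 29 were above that mean. Nfe2, which encodes an erythroid and megakaryocytic transcription factor, had 9429 ± 170 bp (SD, n = 2), and Gata1 had 9180 ± 492 bp, with a domain from 7962535 to 7972441 on X. Tal1 had 8276 ± 419 bp, Hba-a2 8615 ± 390 bp, Hba-a1 7464 ± 648 bp, Hbb-bt 6292 ± 14.8 bp, Klf1 5811 ± 369 bp and Hbb-bs 3477 ± 136 bp. The embryonic globin genes Hba-x, Hbb-bh1 and Hbb-y had 3058 ± 3.54 bp, 3221 ± 513 bp and 1284 ± 46.7 bp. Slc25a37, the mitochondrial iron importer gene, had 0 bp in both replicates, and its whole window has a copy elsewhere in the reference. Hba-a1, Hba-a2 and Hbb-bt also share sequence with other places (30.1%, 34.7% and 43.6% of 32-base words), so their values are uncertain.

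Hepatoblast genes had 3174 ± 116 bp (SD, n = 2), 2.09 times the matched mean in the replicated list (adjusted permutation p = 6e-05), and 20 of 26 genes were above it. The transcription factor genes Prox1 and Foxa3 had the most, 7283 ± 102 bp and 5824 ± 4.95 bp, and Hnf4a had 2629 ± 209 bp. Alb had 1239.5 ± 271 bp and Afp 617 ± 332 bp. The transthyretin gene Ttr and the fibrinogen gene Fgb had no peak within 1 kb of a TSS in either replicate or the replicated list, but 1785 ± 58.7 bp and 1793 ± 659 bp within 5 kb. A neighbouring gene, Sympk, has its TSS within 5 kb of that of Foxa3.

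Haematopoietic stem and progenitor genes had 3821 ± 21.1 bp (SD, n = 2), led by Lmo2 with 8692 ± 364 bp and Meis1 with 7779 ± 132 bp. Runx1 had 5613 ± 137 bp and Spi1 3189.5 ± 9.19 bp. Megakaryocyte genes had 2015 ± 97.8 bp, with Itga2b at 4666 ± 501 bp. Mesenchymal and stellate genes had 2867 ± 115 bp, with Reln at 8203 ± 277 bp and Gata4 at 7754 ± 103 bp. Cell cycle genes had 5282 ± 30.3 bp and housekeeping genes 4952 ± 117 bp. Rrm2, a subunit of ribonucleotide reductase, had 8129.5 ± 19.1 bp, and the spliceosome gene Sf3b1 6713 ± 37.5 bp. E2f4 and Snrpd3, which each have the TSS of another coding gene within 5 kb, had 7456 ± 270 bp and 7225 ± 529 bp. In the replicated list, the progenitor genes stood at 1.70 times their matched mean (adjusted permutation p = 0.000225), the megakaryocyte genes at 2.32 times (0.00533), the mesenchymal and stellate genes at 1.64 times (0.00516), and the cell cycle and housekeeping genes at 1.66 and 1.56 times (both 6e-05). Without CpG matching the megakaryocyte list stood at 1.02 times the mean of random lists (adjusted permutation p = 0.958). The mesenchymal call was lost within 10 kb and from the 5′ end of the gene (adjusted permutation p = 0.0533 and 0.0641).

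Pluripotency and germline genes had 524 ± 46.5 bp (SD, n = 2) and transcription factors of other lineages 1641 ± 155 bp. Neural genes had 1796 ± 44.3 bp, Hox genes 2023 ± 65.2 bp, and receptor genes 8.25 ± 0.0652 bp. In the replicated list, pluripotency and germline genes stood at 0.207 times their matched mean (adjusted permutation p = 6e-05), and transcription factors of other lineages at 0.574 times (0.000103), with 1 of 26 above it. Neural genes stood at 0.704 times (adjusted permutation p = 0.024), Hox genes at 0.769 times (0.0114) and receptor genes at 0.0225 times (6e-05). Pax9 and Six1 had the most among the transcription factors, with 2949 ± 513 bp and 2879 ± 7.07 bp, and the pluripotency gene Sox2 had 2390 ± 84.9 bp. Lists that did not pass in the replicated list were mature hepatocyte genes (0.53 times, adjusted permutation p = 0.171), muscle and heart genes (0.654 times, 0.348), macrophage and granulocyte genes (1.47 times, 0.39), endothelial genes (1.42 times, 0.142), lymphoid genes (0.965 times, 0.965) and cholangiocyte genes (1.06 times, 0.742). Cd68 and Prtn3, the broadest macrophage and granulocyte genes, have the TSS of another coding gene within 5 kb, and without genes that have such neighbours the list stood at 0.504 times and the neural and Hox calls were lost (adjusted permutation p = 0.0944 and 0.0895). The neural and Hox calls were also lost within 10 kb, where the Hox ratio was 1.06, and without CpG matching, which ended the call of transcription factors of other lineages too (adjusted permutation p = 0.445) and put mature hepatocyte, muscle and heart, macrophage and granulocyte and lymphoid genes below random lists.

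**Figure D2:**
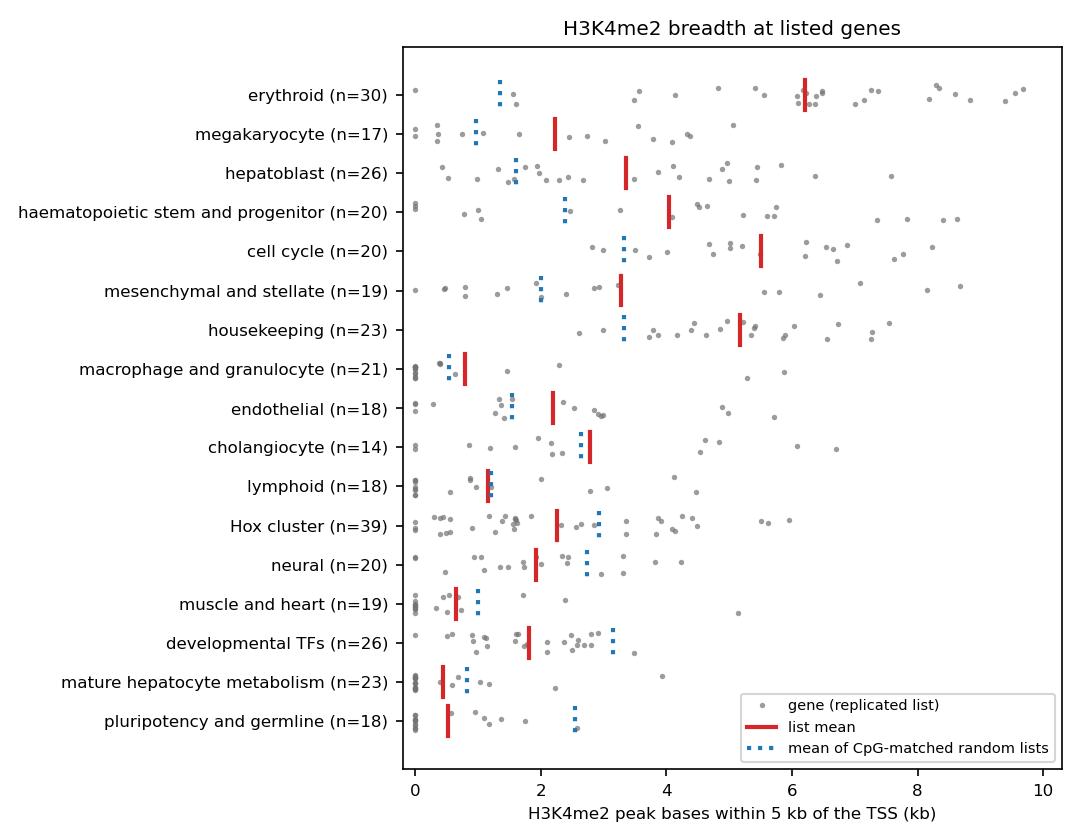
Bases of replicated H3K4me2 peaks within 5 kb of the TSS (horizontal axis, kb) for each gene of 17 lists (grey points; n, genes per list); red bars are list means and dotted blue bars the means of random lists matched on promoter CpG content. Erythroid genes averaged 6211 bp against a matched 1348 bp, and pluripotency and germline genes 526 bp against 2548 bp.

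Distal peaks gathered around erythroid genes. Within 50 kb of the TSS they numbered 4.00 per erythroid gene in the replicated list, 4.09 times the matched mean (two-sided permutation test, adjusted p = 0.00018, from the smallest p the random lists allow), and 6.57 ± 0.896 (SD, n = 2) in the replicates' own lists. Of the 30 genes, 28 were above the matched mean of 0.979, as is any gene with 1 distal peak. The median was 2.5 for erythroid genes and 1 for all 21938 coding genes. Neighbouring genes shared peaks: the windows of the 7 globin genes held 18 different distal peaks, counted 55 times in all, so the genes were not independent and the p is too small. Without globin genes, a setting chosen after the data were seen, the other 23 had 2.83 per gene, 2.6 times the matched mean (adjusted permutation p = 0.00216). The beta-globin genes Hbb-bs, Hbb-bh1 and Hbb-y each had 13 distal peaks in the replicated list and 18.5 ± 2.12 (SD, n = 2) in the replicates. Zfpm1 had 9 and 13.5 ± 4.95, and Klf1 had 0 in the replicated list but 2 in each replicate. Haematopoietic stem and progenitor genes had 2.80 per gene, 2.09 times the matched mean (adjusted permutation p = 0.0178), with 7 at Spi1, where the replicates had 8.5 ± 0.707 (SD, n = 2). Receptor genes had 0.122 per gene, 0.196 times the matched mean (adjusted permutation p = 0.00018). Housekeeping and cell cycle genes did not pass, at 1.71 and 1.77 times (both adjusted permutation p = 0.0626), nor did hepatoblast genes, at 1.58 times (adjusted permutation p = 0.165), and Alb and Afp had 0 in the replicated list but 1 each in either replicate. The other 12 lists lay between 0.532 times for the neural and 1.91 times for the macrophage and granulocyte list, with adjusted permutation p of at least 0.165. The progenitor call was lost within 20 kb and with bases in place of numbers (adjusted permutation p = 0.0737 and 0.161). The housekeeping and cell cycle lists passed with bases in place of numbers (adjusted permutation p = 0.0096 and 0.0287), with −log10 q of at least 5 (0.0292 and 0.0306) and with matching on nearby TSSs (0.049 and 0.0472), the housekeeping list without replicate 1 (0.012) and without replicate 2 (0.0368), and the Hox list, at 0.509 times, without replicate 1 (0.0201).

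At the alpha-globin locus, replicated peaks covered 53.6% of the 76671 bp from Nprl3 to 5 kb past Hba-a2 (chromosome 11, 32225628 to 32302298). They included a series of intervals within Nprl3, the neighbouring gene whose introns hold the alpha-globin enhancers. The replicates covered 37325 ± 1072 bp (SD, n = 2). At the beta-globin locus, peaks covered 24.9% of 124717 bp (chromosome 7, 103807524 to 103932240), with 28865 ± 318 bp in the replicates. The peaks lay at the globin genes, between Hbb-y and Olfr66, and past Olfr65. The receptor genes Olfr64, Olfr65 and Olfr66 in this region, named after their values were seen, had no promoter peak but 18 distal peaks of the replicated list each within 50 kb, in overlapping windows.

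**Figure D3:**
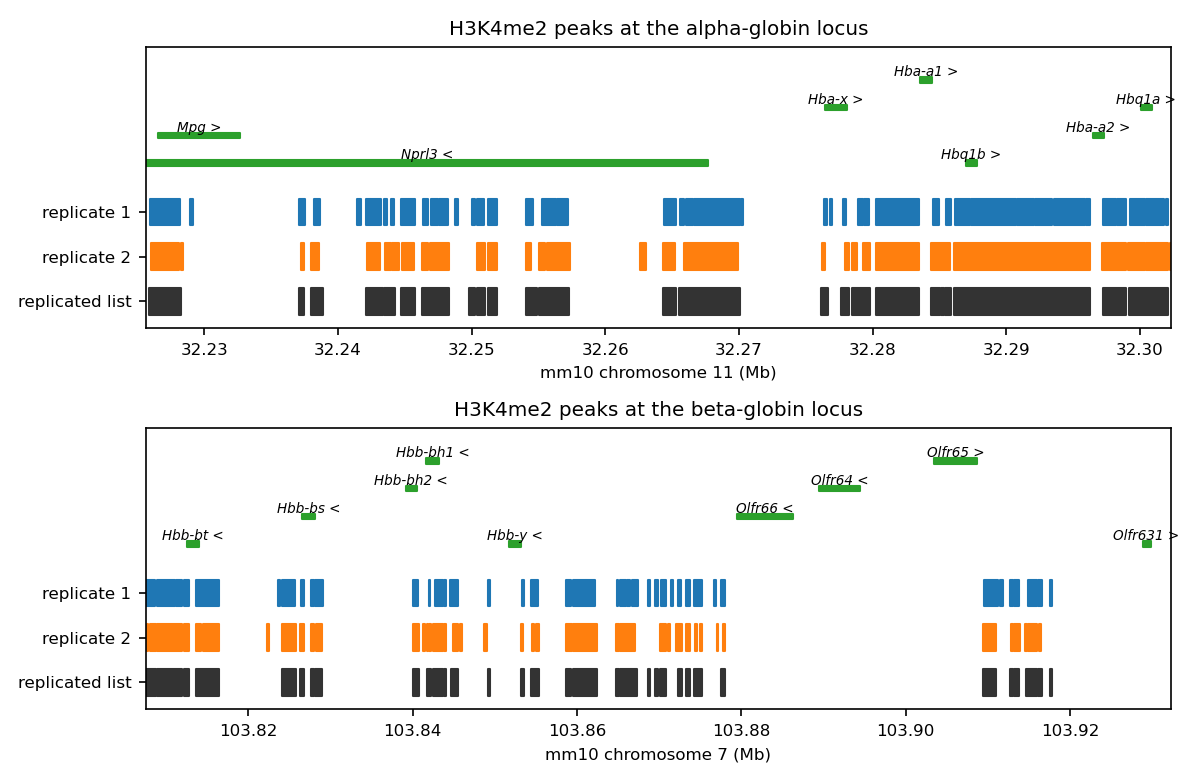
H3K4me2 peaks (blocks) in replicate 1, replicate 2 and the replicated list along mm10 coordinates (horizontal axis, Mb) at the alpha-globin locus (top) and the beta-globin locus (bottom); green bars are coding genes with their direction of transcription. Replicated peaks cover 53.6% of the upper and 24.9% of the lower region.

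Distal peaks held more sites for several blood-related factors than the sequence around them. A GATA site at a fixed spacing from part of an E-box was counted in 17667 distal peaks and in windows 3 kb away. It was 1.43 times as dense in the peaks (95% bootstrap interval 1.35 to 1.51). A full E-box was not required, and no other spacing was counted. This ratio therefore does not show enrichment of the joint site that GATA1 and TAL1 bind in erythroid cells. The single GATA site was at 1.1 times (1.08 to 1.12). The reversed sequences, which have the same base composition, were depleted at 0.677 times (0.627 to 0.726) and 0.756 times (0.739 to 0.773). The ETS site was enriched 2.90 times (2.10 to 4.09), the NFE2 site 2.53 times (2.11 to 3.08) and the RUNX site 1.22 times (1.14 to 1.30), and the replicates' own lists gave 3.27 ± 0.585, 2.43 ± 0.00663 and 1.21 ± 0.000562 (SD, n = 2). The ETS site holds a CpG, which its reversed sequence, at 0.845 times (0.730 to 0.986), lacks. CpG content was therefore not controlled for at this site. The reversed NFE2 sequence, with 7 matches in peaks and 10 in flanks, was at 1.16 times (0.367 to 3.31), and the interval of the NFE2 site over its reverse included 1 (2.19, 0.757 to 6.91). The reversed sequence is rare and holds a CpG that the NFE2 site lacks, so this comparison cannot decide. The CTCF site had the highest ratio, 4.16 times (3.49 to 4.99), followed by the NRF1 site at 3.65 times (2.09 to 6.94) from 42 matches. The reversed CTCF sequence, at 0.354 times (0 to 1.06), had 3 matches in peaks and 14 in flanks. It holds a CpG that the CTCF site lacks. The NRF1 site holds CpGs, and its reversed sequence had 1 match in peaks and 0 in flanks. Composition was therefore not controlled for at either site.

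Among sites of liver factors, the FOXA site was at 1.06 times (1.02 to 1.09) against 0.907 times for its reverse, the HNF4 site at 1.03 times (0.921 to 1.15) and the HNF1 site at 1.24 times (0.568 to 2.41, from 15 matches), and the intervals of HNF4 and HNF1 included 1. HNF1 was at 1.77 in replicate 1 and 0.682 in replicate 2. The CEBP site was at 2.02 times (1.67 to 2.43) and the KLF site at 2.40 times (2.33 to 2.48), and their reversed sequences were also enriched, 1.53 and 2.20 times. The sites exceeded their reverses 1.32 times (1.06 to 1.67) and 1.09 times (1.06 to 1.12). Sites of blood and liver factors were not tested against each other. The MEF2 site was at 1.14 times (0.948 to 1.35), and at 1.24 times (1.04 to 1.47) against flanks 10 kb away. The neural E-box, SOX and POU sites were below 1, at 0.80 times (0.752 to 0.846), 0.835 times (0.791 to 0.879) and 0.841 times (0.774 to 0.921). The REST site had 2 matches in peaks and 0 in flanks, too few for a ratio. With repeat-masked bases left out, the neural E-box was at 1.06 times (0.986 to 1.13) and the POU site at 0.923 times (0.843 to 1.02), and both intervals included 1.

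**Figure D4:**
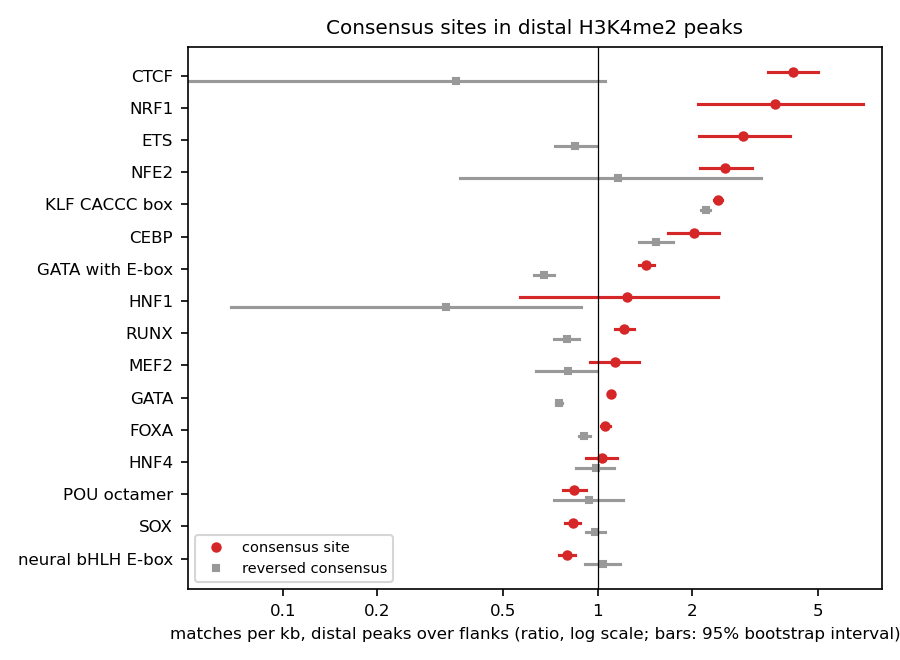
Ratio of matches per kb in distal H3K4me2 peaks to that in flanking windows (horizontal axis, log scale) for 16 consensus sites (red) and their reversed sequences (grey, where flanks held enough matches); bars are 95% bootstrap intervals, and a bar that reaches 0 runs to the axis edge. The CTCF site is at 4.16, GATA with E-box (only part of the E-box required) at 1.43 and the neural E-box at 0.80.

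The X chromosome carried fewer H3K4me2 peaks than any autosome. It had 6.16 replicated peaks per Mb, against 11.9 (chromosome 14) to 28.4 (chromosome 11) on the 19 autosomes, and 0.359 times the autosomal median of 17.1. The replicates gave 0.342 ± 0.00541 times (SD, n = 2). Of 948 X-linked coding genes, 53.0% had a promoter peak, against 56.3 to 82.9% on the autosomes. Gata1 on X was among the 2 erythroid genes with the most covered bases. Both sexes were pooled, so values for males and females were not separable.

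**Figure D5:**
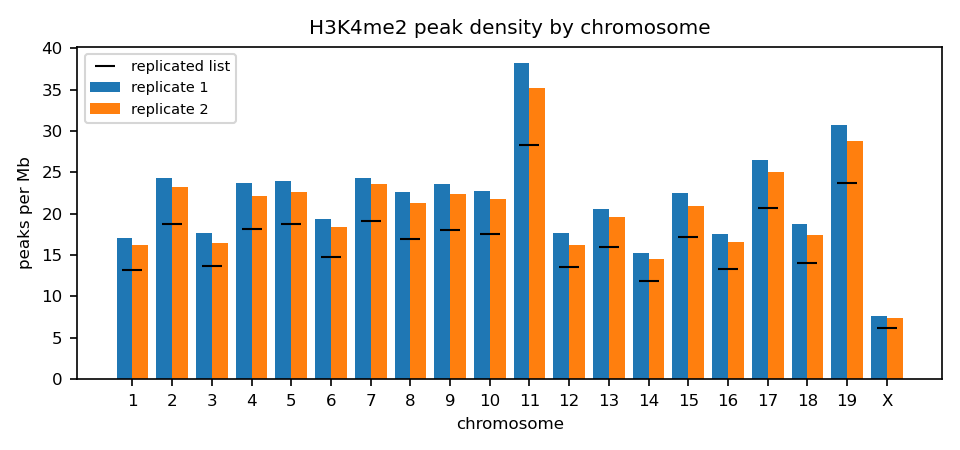
H3K4me2 peaks per Mb (vertical axis) on each autosome and X in replicate 1 and replicate 2 (bars) and the replicated list (black marks). In the replicated list X had 6.16 peaks per Mb and the autosomes 11.9 to 28.4.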

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

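The deposited lists held signal outside the assembled chromosomes that no comparison above used: 11 replicated peaks on 6 unplaced or unlocalized scaffolds, with a median fold enrichment of 9.17 (3.99 to 17.2) and 10338 bases in all. Replicate 1 had 11 such peaks and replicate 2 had 15.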

How the results depend on the processing

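Settings that left out receptor genes, globin genes or genes with a near neighbour, and the choice of which lists have each change given, were made after the data were seen. Most results kept their direction and their side of the threshold: of 560 comparisons of a list or site with an alternative, 499 did. The erythroid list kept all its calls under 7 alternatives for share, 10 for breadth and 9 for distal peaks, with breadth ratios of 2.84 to 5.35 and distal ratios of 2.6 (without globin genes) to 5.16. No paired analysis was possible because there is 1 group. With 2 replicates, leaving one out means using the other's list alone. The cause of the changes below was not tested. Unknown depth limits all counts of weak peaks.

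Requiring an overlap of at least 50% of the peak moved the shared percentages to 73.1 and 77.4, of both peaks to 64 and 67.8, and −log10 q of at least 5 in both lists to 88.5 and 92.2. The Spearman coefficient was 0.948 with −log10 p and 0.939 with 50% overlap. The share of pooled peaks kept was 96.0% at −log10 q of at least 5. The promoter share of peaks was 43.8% within 500 bp, 56.3% within 2.5 kb, 41.5% with coding TSSs only, 38.8% in the pooled list, 49.1% at −log10 q of at least 5, 49.2% by bases, and 41.1 to 42.3% with a replicate left out. The share of genes with a promoter peak was 68.3%, 70.2%, 65.3% (longest coding TSS), 70.0% (pooled list), 68.6% (−log10 q) and 69.2 to 69.2% with a replicate left out. The X ratio was 0.369 at −log10 q of at least 5 and 0.338 to 0.346 with a replicate left out.

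By Fisher's exact test 7 lists lay above and 6 below the other genes, and by permutation against lists matched on CpG content, which changes both the test and the background, 3 and 2. The hepatoblast share, 88.5%, lost its call with receptor genes left out and without replicate 2 (adjusted exact p = 0.050002), and the progenitor share gained one without replicate 1. The range of these shares with a replicate left out was 88.5 to 92.3% and 85 to 95%. Lists below the matched breadth fell from 5 to 3 within 10 kb and to 3 without near neighbours. Breadth ratios that crossed 1 were macrophage and granulocyte (0.851 within 2.5 kb, 0.363 without matching, 0.504 without near neighbours), lymphoid (1.01 without near neighbours), endothelial (0.999 without matching), cholangiocyte (0.926 within 10 kb) and Hox (1.06 within 10 kb, 1.03 without matching).

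Lists above the matched distal count numbered 2, but 1 within 20 kb, 4 both at −log10 q of at least 5 and with matching on nearby TSSs, and 3 by bases and with either replicate left out. Lists below numbered 1, but 1 to 2 with a replicate left out and 0 without receptor genes, which removed that list. The progenitor ratio lost its call within 20 kb (2.22) and by bases (1.82). Distal ratios that crossed 1 were lymphoid (1.21 within 100 kb, 1.2 by bases), mesenchymal (0.899 by bases) and muscle (0.967 by bases, 0.924 at −log10 q of at least 5, 0.956 with matching on nearby TSSs, 0.972 without receptor genes). With repeats left out 1 site, against 3, had an interval below 1, and the neural E-box was at 1.06 and HNF1 at 0.663. HNF1 was at 0.682 without replicate 1 and 1.77 without replicate 2. In all, 18 values crossed 1, 0 of them past the threshold on both sides. Among lists and sites other than erythroid, hepatoblast and progenitor, 26 calls were lost and 16 gained, 3 and 1 of them in values that crossed 1. HNF1 gave no ratio within 500 bp of the midpoint.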

Other observations

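The Hox split, the factor and product split and both tests of the hepatoblast pattern were chosen after the values were seen. Within the Hox list, the Hoxa and Hoxb clusters had a higher mean H3K4me2 breadth than Hoxc and Hoxd. The 11 Hoxa genes had 3261 ± 80.2 bp within 5 kb of the TSS (SD, n = 2 replicates) and the 10 Hoxb genes 2562 ± 244 bp. The 9 Hoxc and 9 Hoxd genes had 949 ± 7.15 bp and 985 ± 79.7 bp. In the replicated list the 21 Hoxa and Hoxb genes averaged 3242 bp and the 18 others 1095 bp (two-sided permutation test, p = 2e-05, difference 2147 bp, 95% bootstrap interval 1356 to 2937). Neighbouring Hox genes share peaks within these windows, so the genes are not independent and the p is too small. The clusters also differ in the members they hold, which was not accounted for. As means of the replicates, Hoxa9 to Hoxa13 had 322 to 2715.5 bp, and Hoxb9 and Hoxb13 had 1017 and 176 bp. Hoxc9 to Hoxc13 had 0 to 1453.5 bp and Hoxd9 to Hoxd13 had 401 to 2050.5 bp, so these members overlapped between clusters.

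Transcription factor genes had a higher mean breadth than the other members of the erythroid and the hepatoblast list. The 8 hepatoblast factors had 4991 ± 27.3 bp (SD, n = 2 replicates) and the 18 other hepatoblast genes, mostly secreted proteins, 2367 ± 180 bp. The 6 erythroid factors had 7580 ± 35.2 bp and the 24 other erythroid genes 5543 ± 87.0 bp. These differences were not tested. Median promoter CpG ratios differed as well, 0.653 against 0.260 in the hepatoblast and 0.274 against 0.176 in the erythroid list. After subtraction of each gene's CpG decile mean the factors and the other genes had 2475 and 1426 bp in the hepatoblast list and 6195 and 4530 bp in the erythroid list, as replicated-list values. The differences in both lists were smaller than in the values above, which are means of the replicates.

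Slc25a37 was the 1 erythroid gene without any peak within 5 kb of its TSS (chromosome 14, 69285112). The data fit a technical explanation: 100% of the 32-base words in its window occur elsewhere in the reference, against a median of 7.16% in the erythroid list, and a complete copy of the window lies at 69498362 to 69508362 on the same chromosome. Reads from either copy may have been dropped because they map to both. Mup20, in the mature hepatocyte list, had 62.3% of such words and no peak, and Serpina1a, in the hepatoblast list, 59.6% and 1385 bp as the mean of the 2 replicates. Whether only unique matches were kept was not given in the sources used here, and no biological explanation was tested.

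Hepatoblast genes had narrower H3K4me2 than erythroid genes in the replicated list, 3355 against 6211 bp, a difference of -2856 bp (two-sided permutation test, p = 3e-05). These values argue against promoter CpG content as the cause. After subtraction of each gene's CpG decile mean the difference was no smaller, at -3114 bp (95% bootstrap interval -4235 to -1937, two-sided permutation p = 1e-05, the smallest the permutations can give). A smaller share of marked cells in the tissue may contribute: where a promoter peak was called, log2 fold enrichment relative to the CpG decile mean differed by -1.43, hepatoblast minus erythroid (95% interval -1.99 to -0.83, two-sided permutation p = 4e-05). The same values could come from weaker marking within every hepatoblast, and bulk peaks cannot separate these. Height and breadth describe the same peaks, so the lower fold enrichment is not separate evidence. Median fold enrichment in the pooled list also differed within the hepatoblast list, 20.3 for the factors and 5.54 for the other genes, without correction for CpG content. Cell proportions were not measured.

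X carried 0.359 times the autosomal median of peaks per Mb. Promoter CpG content was not the whole cause, since the share of X genes with a promoter peak was 0.849 times that of matched autosomal genes (53.0% against 62.4%, central 95% of random lists 60.1 to 64.6%). Distal peaks within 50 kb of X genes were 0.359 times those of autosomal genes matched on CpG content and TSS number (0.405 against 1.13 per gene, 1.03 to 1.24), so these and gene spacing were not the whole cause there. Lower X dosage in pools that include males may hide weak peaks. The X to autosome ratio of distal peaks was 0.312 in the highest of 4 equal groups by fold enrichment and 0.214 in the lowest (1.46 times). The groups were formed over all chromosomes, and whether fold enrichment over control already corrects for dosage is unknown. If it does not, lower dosage would move X peaks into the lowest group, so this comparison cannot decide. The ratio was far below 1 in the highest group too, and X inactivation in females, which the pools cannot show, stays open and untested.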
